A study of Mus musculus with 2 samples.

How the data were processed

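The series holds 2 arrays of total RNA from mouse femur, 1 for an allograft and 1 for an autograft sample, which were grouped by their titles in the labels. The deposited values are intensities on a linear scale, 1 per probe set and array. The array type follows from the probe set names, which have the form used on Affymetrix arrays. The software, the background correction and the scaling that the authors used to make the intensities are not given in the sources used here, nor are the graft procedure, the time after grafting and the number of animals behind a sample. The 2% trimmed mean over all probe sets was 500.2 on the allograft array and 500.1 on the autograft array, so the deposited intensities were already scaled to a common level. They were used as deposited, by a rule fixed beforehand for tables whose trimmed means lie within 10% of each other.

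Of the 22690 probe sets, 64 were controls and were left out of the gene comparison. Of the 22626 others, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 were not listed there; the last 2 kinds were not given gene names. The Entrez identifiers of 20351 of the 20380 probe sets matched the RefSeq gene table of assembly GRCm38.p6, 29 did not, and 0 symbols changed. No coordinates are given, since no genome build is named for the array values. The 20380 probe sets stand for 12393 genes, each represented by its probe set with the highest mean value; 4956 genes have more than 1 probe set, and disagreements between them are described for some of the genes named.

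The floor was the median of the non-control intensities of both arrays, 175.2. Lower values were set to the floor, log2 was taken, and the log2 ratio is allograft minus autograft. Of the non-control probe sets 48.9% were above the floor on the allograft array and 51.1% on the autograft array. A gene was counted as higher or lower at a 2-fold difference, and where it was above the floor on 1 array only its ratio against the floor is a bound. Across 10640 probe sets above the floor on both arrays the log2 values of both arrays had a Pearson r of 0.961, which is a correlation across probe sets that are not independent replicates. No p-value, standard error or interval across genes is given for a difference between the graft types, because each has 1 array. The interval given for the agreement of probe sets concerns that agreement alone.

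A total of 34 gene lists for cell types and processes were fixed before the data were examined, with 767 entries, of which 681 had a probe set. A list's value is the median log2 ratio of its members above the floor on at least 1 array, with bounds taken at their value. It was placed among the medians of 10000 random lists of the same size, drawn from the genes above the floor within 20 bins of mean log2 value, and a list was said to stand apart below percentile 2.5 or above percentile 97.5. These percentiles describe these arrays only. Lists with under 3 members were not placed, which left out the sex-linked list.

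The genes named were fixed by a rule: the 12 highest and 12 lowest ratios with both arrays above the floor, the 5 highest bounds each way among genes above the floor on 1 array, the 2 highest and 2 lowest members of each list, of which the text gives a selection for lists among their random lists, and Tnfsf11, Tnfrsf11b, Vegfa, Acp5, Ctsk, Col1a1, Col2a1, Bglap, Spp1, Cd3e, Cd68, Pecam1, Hba-a1 and Acta1. Genes outside the rule are said to have been chosen after their values were seen. For the agreement of probe sets, the brightest and the next probe set of each gene were compared where both were above the floor on both arrays.

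The alternatives fixed beforehand were quantile normalization, centring on the median of probe sets above the floor or on the 75th percentile, floors at the 25th and 75th percentile, no floor with log2 of the intensity plus 16, the mean or the dimmest probe set of a gene, thresholds of 4-fold and 1.5-fold, list values over all members on the array, list means, and random lists not matched on intensity. Added after the data were seen were a lowess fit of the ratio on mean log2 value with a span of 0.4, probe sets without the brightest 5% or 10%, and probe sets not marked as shared. Simulated arrays held 12393 genes, 200 of them changed by 4-fold or 8-fold, with an SD of 0.2 per array. The counting step recovered 100% of the changed genes at each size and called 1 unchanged gene. All changed genes were drawn from genes far above the floor, and the SD was set rather than estimated from these arrays. These figures therefore check the computation and give no error rate for the real arrays. A list shifted by 0.8 came out at 0.73 and percentile 100, and 1 of the other 32 lists stood apart. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.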

Results

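Total RNA from the femur of C57BL/6 mice was measured on 2 oligonucleotide arrays, 1 for an allograft sample and 1 for an autograft sample. The labels do not say whether this strain is the donor or the recipient of the allograft. An autograft is tissue moved within one animal, and an allograft is tissue moved between animals of one species. Each array gave an intensity for 22690 probe sets, which are groups of short oligonucleotides read together as 1 value for a transcript. The median intensity of the non-control probe sets was 167 on the allograft array and 184 on the autograft array, and the highest intensities were 10522 and 8924.5. With 1 array per graft type, no difference given here has a replicate check, no test between the graft types could be made, and the number of arrays limits the precision of each value. Values at or above 175, the median of all non-control values, are called above the floor.

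The comparison of the arrays asks which transcripts differed in level between the allograft and the autograft sample. Col1a1, the main chain of the type I collagen of bone, had the highest log2 ratio of allograft over autograft among genes above the floor on both arrays, at 2.70 (intensity 4994 against 771), and its second probe set read 2736 against 31.3. Iglv1, an immunoglobulin light chain gene, was next at 2.60 (1391 against 229.7). Its other probe set was below the floor on both arrays. Further down among the 12 highest were Jchain, which joins immunoglobulin units, at 1.72 (1193 against 361) and Igha, the constant chain of immunoglobulin A, at 1.72 (2508 against 759). The B and plasma cell list as a whole lay among its random lists. Prg4, which encodes the joint lubricant lubricin, stood at 2.29 (5303 against 1081), and Retn, which encodes the secreted protein resistin, at 2.07 (1381 against 328). At the other end, Slc16a3, a lactate transporter, had a log2 ratio of -1.93 (236 against 900.1), Col9a3, a collagen of cartilage, -1.67 (414 against 1315), and Col10a1, the collagen of hypertrophic cartilage, -1.51 (362 against 1029).

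In all, 7100 of the 12393 named genes were above the floor on both arrays. Of these, 61 were at least 2-fold higher and 44 at least 2-fold lower in the allograft sample, so that 58.1% of the 2-fold differences were higher. Across the 7100 genes the median log2 ratio was -0.07, the SD across genes was 0.37, and the central 95% of ratios ran from -0.75 to 0.71. The counts depended on the scaling: centring on the 75th percentile gave 77 higher and 33 lower (70.0% higher), and removing the trend of the ratio with intensity, a setting chosen after the data were seen, gave 74 and 28 (72.5% higher). With the floor at the 25th percentile, 109 genes were higher and 170 lower, so the larger group was then the lower one.

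Among the 12 genes with the highest ratios, those not yet named were Myhas, listed as an antisense transcript of the myosin heavy chain genes (2.17), Snrnp40, a splicing factor (2.04), Cyp2e1, a cytochrome P450 (1.82), Thrsp, a gene of lipid synthesis (1.77), Atp2a1, the calcium pump of fast muscle (1.71), and E2f8, a transcription factor of the cell cycle (1.65). The second probe set of Snrnp40 stood at 0.26. Of the 12 lowest, the remaining 9 were Get3 (-1.61), Rcor2 (-1.60), Dusp7 (-1.58), Ubr7 (-1.51), Ocstamp, which takes part in osteoclast fusion (-1.46), Fos, an immediate early transcription factor (-1.40), 1810058I24Rik (-1.36), Tle5 (-1.33) and Impdh1, an enzyme of guanine nucleotide synthesis (-1.33). The probe sets used for Iglv1, Igha and Dusp7 carry a mark for oligonucleotides that can match several transcripts. A second probe set of Col9a3 stood at -0.21, and the further probe sets of Dusp7 and Ubr7 were below the floor on both arrays.

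A further 227 genes were above the floor in the allograft sample alone and 509 in the autograft sample alone. Against the floor, 5 of the former were at least 2-fold higher in the allograft: Rps2, at least 3.43-fold, Psmf1, at least 2.39-fold by the probe set used, Aldh1a7, at least 2.23-fold, Dck, at least 2.22-fold, and Zfp991, at least 2.07-fold. The only probe set listed for Rps2 alone carries the mark for oligonucleotides that can match several transcripts. Another probe set of Psmf1 was above the floor on both arrays, at a log2 ratio of 0.15. Of the 11 genes at least 2-fold higher in the autograft alone, the 5 with the highest bounds were Smyd1, a muscle methyltransferase, at least 2.59-fold, Tbxa2r, the thromboxane receptor, at least 2.32-fold, Plxna2, at least 2.32-fold, Tcp11, at least 2.22-fold, and Ctsf, at least 2.13-fold. On both arrays 4557 genes were below the floor.

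**Figure D1:**
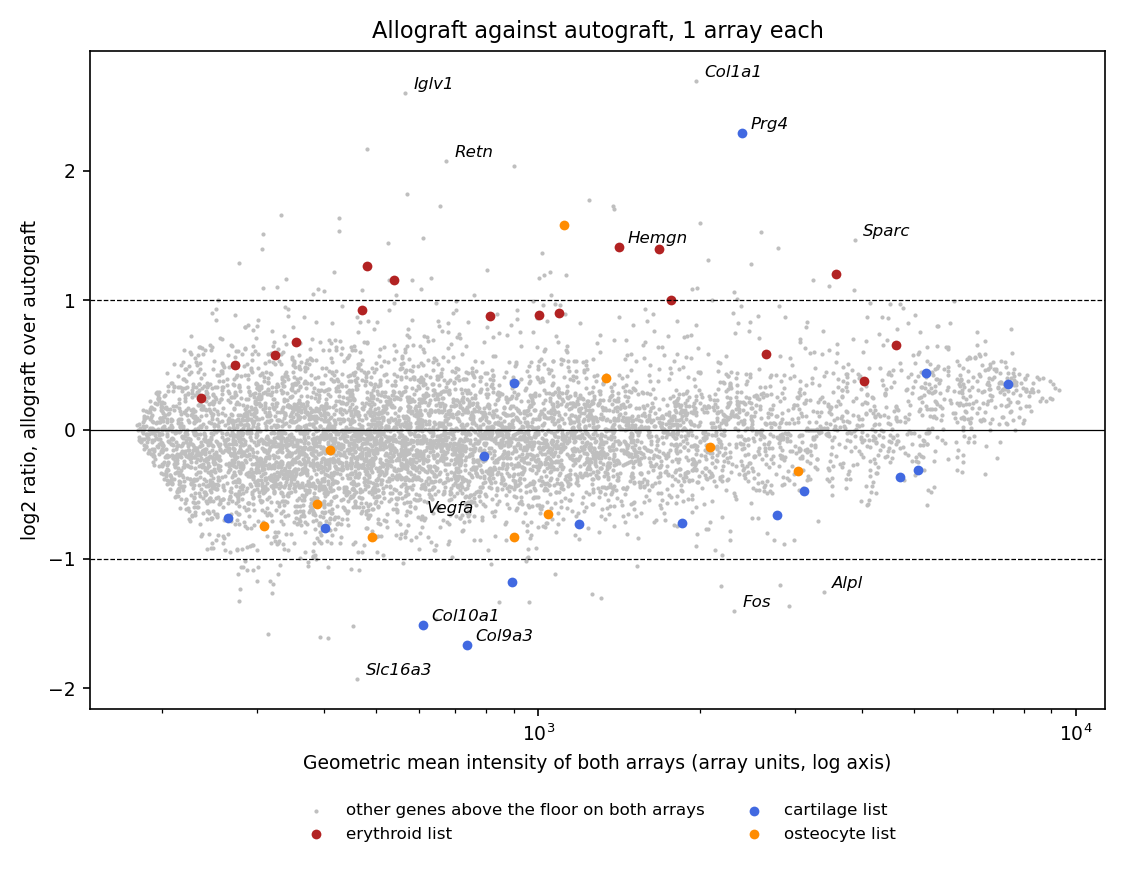
Log2 ratio of allograft over autograft (vertical axis) against the geometric mean intensity of both arrays in array units (horizontal log axis) for the 7100 genes above the floor on both, with 1 array per graft type; coloured points are members of the erythroid, cartilage and osteocyte lists, and dashed lines mark a 2-fold difference. Members of the erythroid list lie above 0, while Col9a3 and Col10a1 lie at -1.67 and -1.51 and Prg4, also of the cartilage list, at 2.29.

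Genes of red cell precursors were higher in the allograft sample. All 18 erythroid members above the floor had a ratio above 0, 5 of them at least 2-fold, and the list's median of 0.88 lay above all 10000 random gene lists of the same size and mean intensity. Hemgn, a nuclear protein of blood progenitors, stood at 1.41 (2308 against 867) and Ermap, a red cell membrane protein, at 1.39 (2721 against 1036), while Sptb, the erythroid spectrin, and Tfrc, the transferrin receptor, were lowest at 0.24 and 0.38. Genes of the cell cycle lay in the same direction, with 24 of 27 members above 0 and a median of 0.40, also above all random lists. Mcm2, a subunit of the replicative helicase, stood at 1.37 and Rrm2, a subunit of ribonucleotide reductase, at 1.31, against -0.38 for E2f1 and -0.09 for Bub1b. The second probe set of Mcm2 stood at 0.43. The neutrophil and granulocyte list had a median of 0.38, at percentile 99.9 of its random lists, with 15 of 15 members above 0, none of them 2-fold. Its highest members were Mpo, the myeloperoxidase of granules (0.86, 6039 against 3316), and Ctsg, a granule protease (0.72), and its lowest were Mmp9 (0.10, with a second probe set at -0.35) and Itgb2l (0.17). The random lists matched to the neutrophil list centred on 0.08. Without the brightest 10% of probe sets the neutrophil median was 0.18 and lay among its random lists.

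Skeletal muscle genes had a median of 0.34 over 26 members, 18 of them above 0, at percentile 99.95 of the random lists. Atp2a1 (1.71, 2501 against 767) and Acta1, the actin of skeletal muscle (1.08, 5615 against 2658), were highest, and the myogenic transcription factors Myod1 (-0.63) and Myog (-0.29) were lowest. Ribosomal protein genes had a median of 0.37 over 17 members, 15 of them above 0 (percentile 98.8), with Rps2 at the bound given above, Rpl19 at 0.99, Rps14 at -0.34 (0.23 in its second probe set) and Rpl37 at -0.41. Interferon response genes had a median of 0.14 over 19 members, 13 of them above 0 (percentile 99.2), between Rsad2 (0.96, 3314 against 1707, with another probe set at 0.04) and Usp18 (0.79) at one end and Oas1a (-0.60) and Oasl2 (-0.45) at the other. The random lists themselves centred on 0.10 for muscle, 0.21 for ribosomal and -0.13 for interferon genes. A value above 0 is therefore not by itself a rise over genes of like intensity. The muscle and ribosomal medians lay among their random lists after quantile normalization, at 0.08 and 0.06.

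The medians of the cartilage, osteocyte and osteoblast lists were below those of their random lists, with members on both sides of 0. The cartilage list had a median of -0.65, below all 10000 random lists, with 13 of 17 members below 0. Besides Col9a3 and Col10a1, its extremes were Prg4 at 2.29 and Col2a1, the main collagen of cartilage, at 0.44 (6121 against 4511). The osteocyte list had a median of -0.45 over 10 members, 8 of them below 0 (percentile 0.050), with Ptprz1 (-0.83) and Dmp1, a matrix protein of osteocytes (-0.83, 677 against 1204), lowest and Kera, a small proteoglycan, highest at 1.58 (1933 against 647). The osteoblast and bone matrix list had a median of -0.34 over 20 members, below all random lists. Its members were split, with 11 below 0 and 9 above. On the allograft array those above 0 read at least 4994 and those below 0 at most 4160. On the autograft array the intensities overlapped, with Col1a1 at 771 and Alpl at 5241. At least 2-fold apart were 3 higher and 2 lower. Omd, osteomodulin, stood at -1.27 (811 against 1952) and Alpl, the alkaline phosphatase of mineralising cells, at -1.25 (2197 against 5241), whereas Col1a1 (2.70) and Sparc, osteonectin (1.46, 6445 against 2336), went the other way. The mean of this list was -0.03, among its random lists. With the floor at the 75th percentile the osteoblast median was 0.05 and the osteocyte median -0.22, both among their random lists.

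Wnt and hedgehog signalling genes had a median of -0.32 over 18 members, 14 of them below 0 (percentile 0.74), with Sfrp1, a secreted Wnt antagonist (bound of -0.84), and Smo, the hedgehog signal transducer (-0.75), lowest and Lrp6 (0.42) and Sfrp2 (0.22) highest. The probe set used for Sfrp1 read 34.4 against 313.7, while another was above the floor in the allograft alone (175.8 against 65.2). Immediate early and heat shock genes had a median of -0.25 over 21 members, 12 of them below 0 (percentile 1.93). Fos (-1.40, 1424 against 3757) and Zfp36, which destabilises messenger RNA (-0.99), were lowest, and the chaperone genes Dnajb1 (0.75) and Hspa1b (0.63) highest, although further probe sets of these chaperone genes stood at -0.49 and at a bound of -0.32. The immediate early median was 0.01 with the floor at the 75th percentile, and the Wnt and hedgehog median was 0.00 with all members on the array included.

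**Figure D2:**
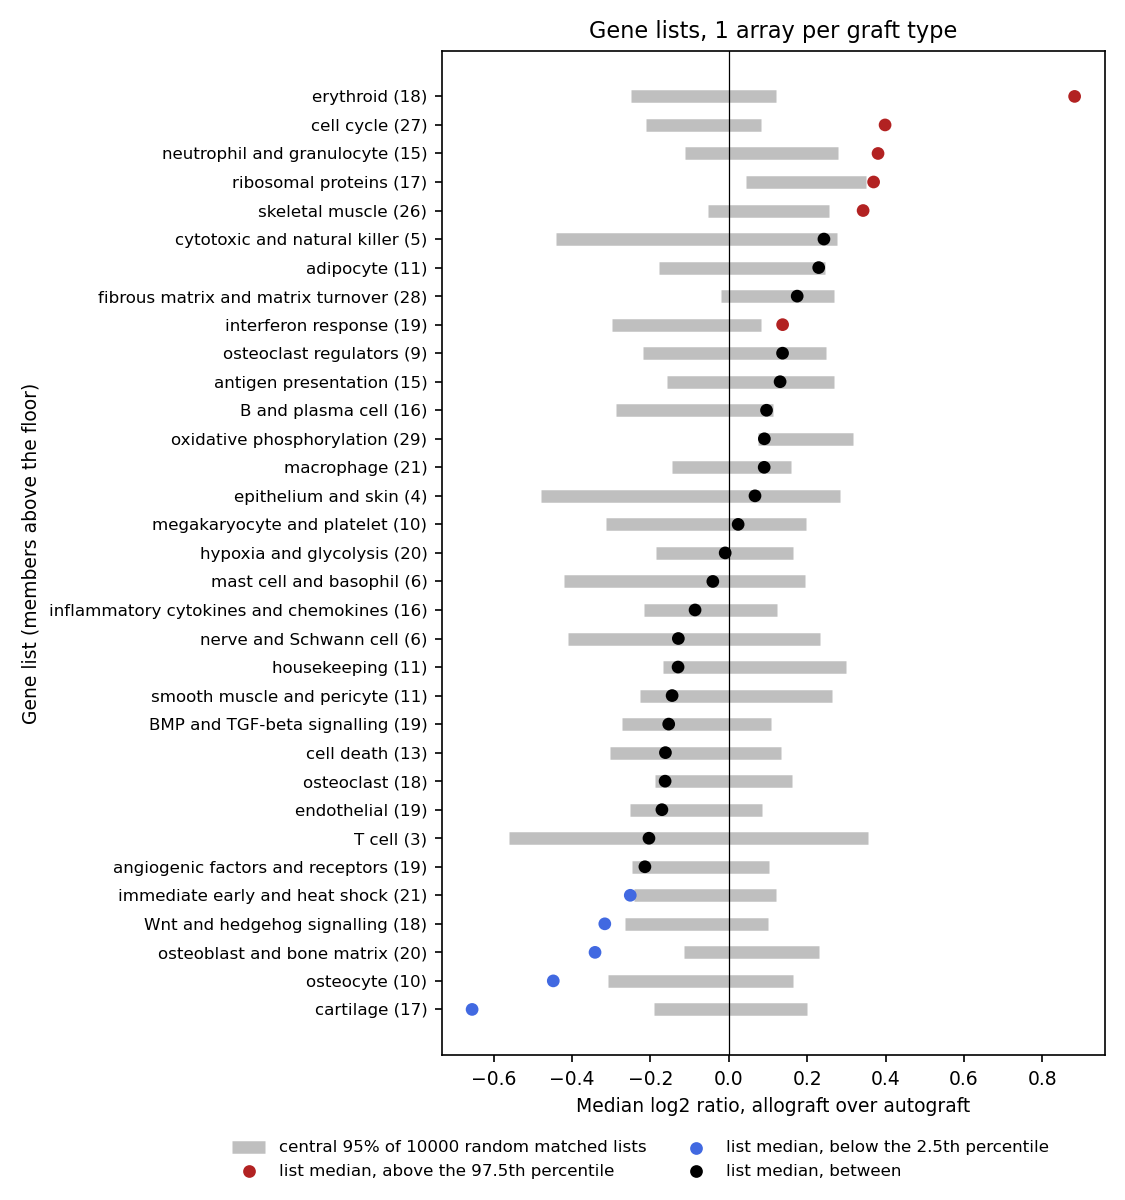
Median log2 ratio of allograft over autograft (horizontal axis) for 33 gene lists, with the number of members above the floor in parentheses; grey bars span the central 95% of the medians of 10000 random lists matched on mean intensity, red and blue points lie outside it above and below, and black points lie between. The erythroid list, at 0.88, lies farthest above its random lists and the cartilage list, at -0.65, farthest below.

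Genes of vessel growth and of bone resorption were among those fixed beforehand. Vegfa, the main growth factor of blood vessels, had a log2 ratio of -0.68 (473 against 756) and Pecam1, an endothelial adhesion protein, -0.31 (194 against 241). Angiogenic factors and receptors had a median of -0.21 over 19 members, 13 of them below 0 (percentile 5.13), between Hif1a (0.46) and Vegfa. Endothelial genes had a median of -0.17 over 19 members, 16 of them below 0 (percentile 14.0), with Robo4 at -1.23. Both lists lay among their random lists, so a majority of members below 0 does not by itself set a list apart. Of the osteoclast genes, the resorption enzymes Acp5 (0.97, 6312 against 3219) and Ctsk (0.31, 7694 against 6198) were above 0, and Ocstamp (-1.46) and Oscar, an osteoclast receptor (-0.95), were lowest. The osteoclast median was -0.16 over 18 members, 13 of them below 0 (percentile 4.79). It lay below its random lists in most of the alternative settings, as with the floor at the 25th (-0.28) or the 75th percentile (-0.31). Tnfsf11, the osteoclast differentiation factor RANKL (131.9 against 92.2), Tnfrsf11b, its decoy receptor (32.5 against 38.1), and Cd3e, a T cell receptor subunit (35.2 against 99.9), were below the floor on both arrays, so no ratio is given. The probe set listed for the alpha globin Hba-a1 alone was below the floor too (32.3 against 40.5). Probe sets that match both Hba-a1 and Hba-a2 read 8737 against 5601, 612 against 221 and 254.5 against 80.3, the last above the floor in the allograft alone. Bglap and Spp1 had no probe set listed for them alone. Cd68, a macrophage protein, stood at -0.55 (3294 against 4827).

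The other lists lay among their random lists, though the adipocyte list lay above its own in most of the alternative settings. Those with medians above 0 were cytotoxic and natural killer (0.24, 5 members, percentile 96.1), adipocyte (0.23, 11, 96.6), fibrous matrix and matrix turnover (0.17, 28, 75.7), osteoclast regulators (0.14, 9, 86.2), antigen presentation (0.13, 15, 75.3), B and plasma cell (0.10, 16, 96.3), macrophage (0.09, 21, 86.2), oxidative phosphorylation (0.09, 29, 5.0), epithelium and skin (0.07, 4, 84.1) and megakaryocyte and platelet (0.02, 10, 76.5), each with its median, its members above the floor and its percentile. Those below 0 were hypoxia and glycolysis (-0.01, 20, 50.7), mast cell and basophil (-0.04, 6, 69.8), inflammatory cytokines and chemokines (-0.09, 16, 36.7), nerve and Schwann cell (-0.13, 6, 46.5), housekeeping (-0.13, 11, 4.71), smooth muscle and pericyte (-0.14, 11, 9.59), BMP and TGF-beta signalling (-0.15, 19, 27.4), cell death (-0.16, 13, 26.3) and T cell (-0.20, 3, 32.1). Among their members, Scd1 of the adipocyte list stood at 1.40 (4545 against 1719), Mcpt8 of the mast cell and basophil list at 1.51 (519 against 182) and Prdm1 of the B and plasma cell list, below the floor in the allograft sample, at a bound of -0.96. H2-Ab1 of antigen presentation stood at 1.04, but its other probe sets stood at -0.44 and -0.39. Of the sex-linked genes 1 was above the floor, Xist, at 3712 against 3485 (log2 ratio 0.09).

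Probe sets of one gene allowed a check within this pair of arrays. Among 1925 genes with a second probe set above the floor on both arrays, the ratios of both probe sets differed with an SD of 0.43. For 27 of these genes the brighter probe set was at least 2-fold apart, and the second had the same direction in 22 (81.5%, 95% Wilson interval 63.3% to 91.8%) and was itself 2-fold apart that way in 6. For 1 gene, Sugp2, it was 2-fold apart the opposite way. The interval treats the 27 genes as independent, which genes read on the same arrays are not. Several abundant transcripts, chosen after their values were seen, had probe sets far apart: those of Bgn, biglycan, stood at 0.21, 0.59 and 4.14, and Rps28 had one probe set at 4038 against 633 and another at 87.9 against 6436. Over 20 intensity bins the median ratio was -0.05 in the dimmest, lowest at -0.14 in the bin around an intensity of 402, and 0.30 in the brightest. The 15 hybridisation control probe sets above the floor had a median ratio of 0.31, and the ratio of 3' to 5' beta-actin control intensity, which rises with RNA breakdown, was 1.77 in the allograft and 1.19 in the autograft. That of the Gapdh controls was 0.194 and 0.0349.

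**Figure D3:**
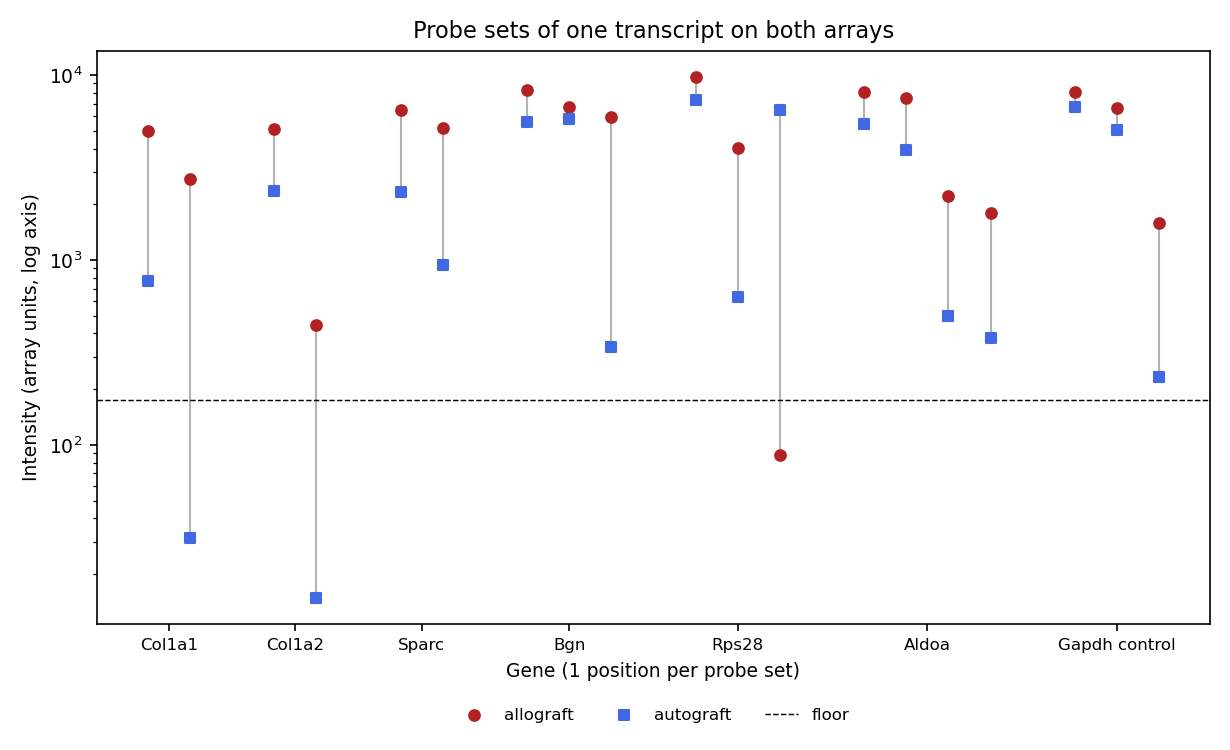
Intensity in array units (log axis) of each probe set of 6 abundant genes and of the Gapdh control, on the allograft array (circles) and the autograft array (squares), 1 array each; a line joins the values of one probe set and the dashed line is the floor of 175. Probe sets of one transcript lie apart by different amounts, as for Bgn with ratios of 0.21 and 4.14; Col1a2, Bgn, Rps28 and the control were chosen after their values were seen.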

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

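The 3 tests on the collagen values and those on marrow content and on the share of skeletal cells were chosen after the values were seen; the tests on the intensity trend and the one on bright erythroid probe sets were set down before their results were seen. The bound in the test on RNA breakdown was added after a first rule without it had counted the beta-actin ratio against that explanation, and the Gapdh controls were added to it with both ratios known. A signal at least 4-fold apart appeared in 5 probe sets outside the gene comparison. A probe set that matches both Gzme and Gzmd, genes of the granzyme family, had a log2 ratio of 2.0 (1232 against 307). The 2 probe sets not listed in the annotation stood at 2.0 (816 against 203) and 2.79 (2968 against 429), and one that matches Rpl31 and a pseudogene of it at 2.39 (4380.3 against 837). The 3' control probe set of Gapdh stood at 2.76 (1577 against 233), while the 5' and middle probe sets of the same transcript stood at 0.28 and 0.39. Of the 866 probe sets without a single gene symbol that were above the floor on both arrays, 23 were 2-fold higher and 8 lower.

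Col1a1 (2.70), Sparc (1.46) and Col1a2 (1.11, named after its value was seen) were higher in the allograft sample, while the median of the list they belong to was below 0. A rise shared by that list is argued against by the median of all its 20 members, these 3 included, which was -0.34, below all random lists. The median also lay 1.45 below the lowest of the 3 (SD of the members 0.97). That distance adds little, because these 3 were the highest members of the list and its median had to lie below them. More broken RNA in the autograft sample stays open: the 3' to 5' ratio of the beta-actin controls in the autograft was 0.673 times that in the allograft, a log2 difference of -0.57 that lies within 2 times the SD of 0.43 between probe sets of a gene, and the difference of -2.47 in the Gapdh controls, though against more broken RNA, rests on a 3' probe set that read below its 5' probe set on both arrays and that loss of signal on the autograft array would lower too. Loss of signal at the brightest probe sets of the autograft array remains a candidate explanation, which the test made for it cannot single out. Among genes with a probe set in the top 5% of intensity, these 3 left out, 21 of 667 further probe sets were 2-fold higher in the allograft and 4 were lower. The share higher is 3.94 times the one among other genes (20 higher and 20 lower of 2505). This comparison was not matched on intensity. The general trend, with a median ratio of 0.30 in the brightest intensity bin, would tilt it the same way. That test does not reach the 3 genes themselves, and a difference between the grafts remains untested for them, as does loss of signal on the allograft array, where an Rps28 probe set read 87.9 against 6436.

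The erythroid list was higher in the allograft sample, at 0.88. A larger amount of marrow as a whole would raise the marrow lists by like amounts if their probe sets responded alike, which was not tested. On that assumption it is argued against as the whole cause by the other marrow lists. The closest, neutrophil and granulocyte, lay 0.50 below the erythroid list (combined SD of random lists 0.14). That SD is a spread over random draws of genes. More marrow as a part of the cause stays open. The neutrophil list stood apart at 0.38, while the B and plasma cell (0.10) and megakaryocyte and platelet (0.02) lists lay among their random lists. Without the brightest 10% of probe sets the median was 0.88 over 13 members, above all random lists. This cannot decide on losses at bright probe sets, which were left out by their mean over both arrays. A probe set that had lost signal on the autograft array could therefore stay in. Members with low intensity on both arrays, such as Kel (1.16, 806 against 362) and Gata1 (0.68, 448 against 280), were above 0, as were all others. The trend of the ratio with intensity is argued against as the whole cause by its size, with median ratios of the 20 intensity bins from -0.14 to 0.30. After the lowess fit the median was 0.95, again above all random lists. That placement adds little, because the random lists were already matched on mean intensity. Globin probe sets above the floor on both arrays, looked up after the list's value was seen, were higher too: one listed for Hbb-b2 at 0.89 and a pair that matches Hba-a1 and Hba-a2 at 0.64 and 1.47. A difference in red cell precursors between the grafts, or between 2 animals or pieces of tissue whatever the graft, may account for it, and with 1 array per graft type these cannot be separated.

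The cartilage and osteocyte lists were lower in the allograft sample, at -0.65 and -0.45. The intensity trend is argued against as the whole cause by its size, since the median ratios of the 20 intensity bins ran from -0.14 to 0.30. After the lowess fit the less negative of both medians was -0.43 and both lay below the 2.5 percentile of their random lists. Those percentiles add little, because the random lists were already matched on mean intensity. A lower share of skeletal cells would raise other tissues alike; a first test, the lowest of 6 such lists against all genes, left this undecided (endothelial, -1.24 SD, against a bound of -2), and a test put in its place found that these lists lay up to 1.09 apart (erythroid against smooth muscle and pericyte, combined SD 0.16), or 0.39 apart without the erythroid list (combined SD 0.15). The spread cannot decide the question, since any of these tissues can change for its own reason while the skeletal share falls. A lower skeletal share therefore stays open, with or without a change in another tissue. Differences between the grafts, the animals or the dissected pieces remain untested.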

How the results depend on the processing

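Tests with the lowess fit, without the brightest 5% or 10% of probe sets and without shared probe sets were chosen after the data were seen; the others were set beforehand. The erythroid (0.79 to 0.95), cell cycle (0.27 to 0.47), interferon (0.01 to 0.26) and cartilage (-0.71 to -0.31) medians kept their side of their random lists under all 15 alternatives. Of the other lists that stood apart, neutrophil did so in 14, osteoblast in 13, osteocyte and muscle in 12 each, Wnt and hedgehog and ribosomal in 10 each and immediate early in 8. For the lists that lay among their random lists, 283 values stayed there and 38 did not. The osteoclast and adipocyte lists stood apart in most of the alternatives. Of the 61 higher and 44 lower genes, 59 and 28 were also called after the lowess fit, 56 and 29 after quantile normalization, and 37 and 26 with the dimmest probe set. Of the single-gene values, 1713 moved by at most the 0.43 SD between probe sets, 138 moved further, and 2 changed sign from a 2-fold difference, both of H2-Ab1: -0.44 with the dimmest probe set and -0.39 without shared probe sets. A further 12 of the 159 genes that the naming rule gave, all under 2-fold as reported, changed sign in at least 1 setting, among them Csf1r (0.65 to -0.59), Dnajb1 (0.75 to -0.49) and H2-K1 (0.80 to -0.37). Signal over background limits what can be read of 4557 genes. No paired analysis was possible because each graft type has 1 array, and no replicate could be left out. Values as deposited served throughout, so no separate setting stands for them. The causes of the changes below were not tested, except that a stricter threshold or a higher floor leaves fewer genes to call and a lower one more.

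Counts are given in the order higher and lower with both arrays above the floor, then allograft alone and autograft alone. The floor at the 25th percentile gave 109, 170, 36 and 66, and at the 75th percentile 29 and 13, with 2 in autograft alone. Without a floor 234 were higher and 418 lower. A threshold of 4-fold gave 6, 0, 0 and 0, and of 1.5-fold 289, 442, 22 and 64. Quantile normalization gave 9 in allograft alone and 5 in autograft alone, and centring on the 75th percentile 7 in autograft alone. The mean over probe sets gave 27 lower and 2 in allograft alone, the lowess fit 28 lower and 6 in autograft alone, and leaving out the brightest 10% 8 in allograft alone.

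Lists that stood apart came among their random lists in these settings. After quantile normalization the medians were 0.080 for muscle, -0.21 for immediate early and 0.055 for ribosomal genes. After centring on the median, immediate early genes stood at -0.15. With the floor at the 75th percentile the osteoblast (0.054) and immediate early (0.0094) medians changed sign, and osteocyte stood at -0.22, Wnt and hedgehog at -0.23 and ribosomal at 0.32. The dimmest probe set gave -0.24 for osteocyte, -0.35 for Wnt and hedgehog and 0.34 for ribosomal genes. The lowess fit gave -0.19 for immediate early and 0.10 for ribosomal genes. Without the brightest 5%, muscle stood at 0.092, immediate early at -0.25 and ribosomal at 0.14, and without the brightest 10%, muscle at 0.029, neutrophil at 0.18, Wnt and hedgehog at -0.23 and immediate early at -0.020. Without shared probe sets Wnt and hedgehog stood at -0.21, and with all members on the array at 0.00, with immediate early at -0.020. The means were -0.028 for osteoblast and -0.23 for osteocyte.

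Lists that had lain among their random lists stood apart in these. The osteoclast list was lower with the 75th percentile centring (-0.21), the floor at the 25th (-0.28) and 75th percentile (-0.31), no floor (-0.21), the mean (-0.16) and the dimmest probe set (-0.33), without the brightest 5% (-0.33) and 10% (-0.28), without shared probe sets (-0.27) and as a mean (-0.19). The adipocyte list was higher with the floor at the 25th (0.55) and 75th percentile (0.39), no floor (0.39), the mean (0.20) and dimmest probe set (0.31), without shared probe sets (0.23), with all members (0.12), as a mean (0.52) and against unmatched lists (0.23). Smooth muscle and pericyte genes were lower after quantile normalization (-0.32), the lowess fit (-0.30) and without the brightest 5% (-0.33) and 10% (-0.33). Endothelial genes were lower with the mean probe set (-0.22), without shared probe sets (-0.29) and as a mean (-0.24). B and plasma cell genes were higher with the floor at the 25th percentile (0.10), without the brightest 10% (0.11), with all members (0.014) and as a mean (0.18), and cytotoxic genes with the mean probe set (0.24) and as a mean (0.24). The T cell list stood at -0.39 with the floor at the 25th percentile, and with the dimmest probe set the BMP and TGF-beta list stood at -0.35 and the inflammatory list at 0.29. Oxidative phosphorylation was below its random lists as a mean (0.072), and against unmatched lists both it (0.091) and fibrous matrix (0.17) were above.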

Other observations

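The selection described here was made after the values were seen and includes genes outside the naming rule, and no test was run on these genes. The 3 probe sets of Igha lay between 1.72 and 2.10 and Jchain stood at 1.72, whereas the 4 probe sets of Ighm, the heavy chain of immunoglobulin M, that were above the floor on both arrays lay between 0.13 and 0.37. Xbp1 and Prdm1, transcription factors of antibody-secreting cells, stood at -0.35, with other probe sets of Xbp1 from -0.48 to 0.17, and at a bound of -0.96. Thrsp stood at 1.77 and 1.60 in its 2 probe sets and Fasn, the fatty acid synthase, at 1.22. Members of the adipocyte list went both ways, with Retn at 2.07, Scd1 at 1.40 and Adipoq, the hormone adiponectin, at 1.15 (4839 against 2176), but Slc2a4 at -0.31. The 3 probe sets of Cd36 disagreed, at -0.40, 0.40 and -0.61. The mean log2 ratio of the adipocyte list was 0.52, above all its random lists, while its median of 0.23 lay among them. Gzme, a granzyme, stood at 1.53 (724 against 250.0), in a probe set with the mark for oligonucleotides that can match several transcripts. The related Gzmc, Gzmf and Gzmg were below the floor on both arrays.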
